A study of Mus musculus with 6 samples.

How the data were processed

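Single-nucleus RNA sequencing was done on frozen hippocampi of aged mice, given in the labels as 18 to 20 months old. The labels list 6 libraries, 3 from mice that breathed 2% sevoflurane, a volatile anaesthetic, in 60% oxygen for 6 h at a flow of 1 L/min, and 3 from mice that breathed 60% oxygen alone for the same time and at the same flow. Replicates 1 and 2 of each group are labelled male and replicate 3 female. No label says how many animals went into a library, so p-values measure the spread between libraries.

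Per the submitters' protocol notes, the libraries were droplet-based libraries of the 3' ends of transcripts, read in pairs of 150 bp. Per the submitters' processing notes, reads were passed through fastp and Cell Ranger 7.1.0 with the mm10 genome. The deposited matrices hold raw counts, that is, unique molecular identifiers (UMIs) per gene and barcode, and per the file headers they are whole numbers written by Cell Ranger 7.1.0. The barcodes had already been selected by the authors. Whether intronic reads were counted and which gene annotation was used are not given in the sources used here. The matrices list 32285 genes, of which 32158 were matched by Ensembl ID to GENCODE M21 for positions and lengths on mm10. The span of a gene is the distance from its start to its end, introns included.

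The deposited matrices held 53824 barcodes, and 53287 of them passed the filters of at least 500 UMIs, at least 300 genes and at most 5% of UMIs from mitochondrial genes. Doublets were scored per library with Scrublet, as implemented in scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes and 30 principal components. The automatic score threshold failed in oxygen replicate 1, where it lay at 0.659 and called 0 doublets, so a common threshold of 0.303 was used in all 6 libraries. This removed 1395 barcodes and left 51892 nuclei. Total counts per library as deposited ranged from 56334621 to 72636984 UMIs. For shares of single libraries, 95% Wilson intervals are given. These intervals, and the upper limit that a count of 0 allows (3 counts), cover counting error only.

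Counts per nucleus were scaled to equal totals and log-transformed. The 3000 most variable genes among those seen in at least 50 nuclei were used, leaving out mitochondrial, ribosomal and sex-linked genes. A graph of 20 shared nearest neighbours on 40 principal components was divided with the Leiden method of igraph 0.11.9 at resolution 1.0, with no integration of the libraries. This gave 45 clusters. A cluster was named when at least 3 markers of 1 cell type, from 23 marker lists, had at least 10 CPM (counts scaled to one fixed total) in it and were at least 2 times higher than in the other nuclei (5 CPM added to both). It was left unnamed when another type's markers stood higher among its 10 leading genes, when over 30% of its nuclei had been called doublets, or when its nuclei held few UMIs and none of the 10 leading genes was a marker of its own type. In this way 27 clusters received 16 names and 18 stayed unnamed. The names rest on markers alone, and the classes are therefore written as X-like. A class was tested when each of the 6 libraries held at least 20 of its nuclei, which 12 classes met.

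Raw counts were summed per library over all nuclei and over each of the 12 classes. Sevoflurane was compared with oxygen by the edgeR 4.0.16 quasi-likelihood test (robust fit) in R 4.3.3, with TMM normalization, the filterByExpr filter and treatment as the only term. P-values were adjusted by the Benjamini-Hochberg method within each set of nuclei, and a gene was called at an adjusted p under 0.05. Fold changes are log2 values of sevoflurane over oxygen with their standard error (SE). For edgeR the SE was derived as the absolute fold change divided by the square root of the test's F statistic. CPM values are means of 3 libraries with the standard deviation (SD), on normalised library sizes. Shares of nuclei were compared by a two-sided exact permutation test over 20 splits, whose smallest possible p is 0.10, and class counts also by edgeR. The difference of the response between the most numerous neuronal class and the most numerous glial class was tested with limma 3.58.1 (trend, robust) on differences of log2 CPM (prior count 2) within each library. A further difference, astrocyte-like minus dentate granule-like, was added after the results had been seen.

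The genes named in the text were chosen by a rule: among called genes with a mean of at least 10 CPM in 1 group and no overlap of the groups' libraries, the 10 largest rises and 10 largest falls in all nuclei and in the classes with most calls, and the 4 largest of each in every other class. Also named were up to 4 members with the smallest p of each gene list that passed its test or held a called member, up to 10 genes per direction called in most classes, Mtap, and sex-linked genes as a check of the labels. Genes that carry only a predicted-gene number were counted and not named, and the single values of 3 further genes are not reported here. This rule, the marker lists, the tests and the other settings tried were set before the data were examined, except those said to be added.

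Sets of genes were tested with camera (limma) with a preset inter-gene correlation of 0.01 and the false discovery rate (FDR) taken over the lists of each set of nuclei. The 25 lists were immediate early genes, glucocorticoid-responsive genes, circadian clock, methionine salvage and polyamines, adenosine signalling and turnover, inflammatory cytokine and NF-kB genes, interferon response, disease-associated microglia genes, reactive astrocyte genes, complex I to V nuclear genes, mitochondrially encoded genes, cytosolic ribosomal proteins, unfolded protein response and ATF4, heat shock proteins, NRF2 antioxidant genes, GABA-A receptor subunits, ionotropic and metabotropic glutamate receptors, two-pore potassium and HCN channels, synaptic vesicle release, myelin genes, cholesterol synthesis, hypoxia and glycolysis, blood-brain barrier genes, apoptosis and p53 targets, and protein arginine methyltransferases and methylation. The symbols Bmal1, Mx1 and Clec7a of these lists are not among the symbols of the matrices.

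The steps were tested on simulated counts drawn from the means and library sizes of these data, with 200 changed genes. With a true log2 change of 1, edgeR recovered 91% of the changed genes over all nuclei, 97% in dentate granule-like, 83% in astrocyte-like and 51.5% in endothelial-like nuclei. With a change of 0.5 it recovered 52%, 47%, 18% and 10.1%. When each gene was given its own spread, 9.8 to 15.5% of calls were false, and when genes of like abundance shared a spread, 0.7 to 4.7% were. With a simulated length trend in dentate granule-like nuclei, 15.1% of the calls were false without and 7.8% with a length correction. The difference test recovered 65.3% of changes of 1 and 3.1% of changes of 0.5. In astrocyte-like nuclei camera found the raised list and passed 0 of 20 random lists. The simulated genes were drawn independently of each other. This run therefore cannot show how camera behaves when the genes of a list are correlated.

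Other settings tried were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, labelled sex as a term, the replicate number as a block, counts thinned to the smallest library, doublets kept, at least 1000 UMIs and at most 1% mitochondrial UMIs, equal class shares, Leiden resolution 0.5, genes far lower in a class than in another class left out, a prior count of 0.5, a mean of at least 20 CPM, an estimated inter-gene correlation, fry, and each library left out in turn. Some settings were added after the results had been seen: a correction for gene length, leaving out the choroid plexus-like nuclei with clusters 16 and 40, and leaving out cluster 2. The length correction was a lowess trend on gene span, entered as an offset. It was fitted per library to the deviation of log2 CPM from the gene's mean over the libraries. Over all nuclei the replicate numbers showed no pairing: libraries of the same number had correlations of -0.246, -0.182 and -0.0621 after each group's mean was removed. In endothelial-like nuclei these correlations were -0.0938, 0.0161 and 0.0817. With 3 libraries per group this cannot exclude that libraries of the same number shared a batch. No pair of libraries were copies of each other, since the chi-square per gene between pairs was at least 18.0. Among 345 named genes with a position, 12 overlap another protein-coding gene on the same strand, and reads of close relatives such as Mt1 and Mt2 or Slfn8 and Slfn9 were not separated further.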

Results

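Gene expression was measured in single nuclei from the hippocampi of aged mice in 6 libraries, 3 made after sevoflurane in 60% oxygen and 3 after 60% oxygen alone. After filtering, the sevoflurane libraries held 9726, 8920 and 8916 nuclei and the oxygen libraries 7783, 8813 and 7734 nuclei, in the order of their replicate numbers. The deposited totals were 68960236, 61398346 and 72636984 UMIs in the sevoflurane libraries and 56334621, 70077201 and 56831794 UMIs in the oxygen libraries. The median nucleus held 4664 to 6090 UMIs, depending on the library. The most numerous class was dentate granule-like neurons (9913 nuclei), followed by oligodendrocyte-like (6816), CA1 pyramidal-like (5265), subicular or cortical excitatory-like (4757) and astrocyte-like nuclei (4127). The comparison asks what 6 h of sevoflurane changed in the aged hippocampus, in a study whose title concerns low blood S-methyl-5-thioadenosine and delayed cognitive recovery after surgery.

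The labelled sex did not match sex-linked expression in 3 of the 6 libraries. Xist, which silences one X chromosome in females, reached 1363 CPM in sevoflurane replicate 1, labelled male, and 1.22 CPM or less in the other 5 libraries. The summed CPM of 4 Y-linked genes was 0.349 in sevoflurane replicate 1 and 342 to 373 in the others, including sevoflurane replicate 3 and oxygen replicate 3, labelled female. The sevoflurane group therefore held 1 library with a female pattern and the oxygen group 0. None of the 6 sex-linked genes checked was called in any set of nuclei. With 1 female-pattern library in the group, such genes spread widely after sevoflurane (Uty 83.7 ± 73.1 CPM, SD, in oligodendrocyte-like nuclei) and could hardly be called. The absence of calls therefore does not show that sex left other genes unchanged. Of the 412 genes called over all nuclei, 12 lie on the X chromosome, a count that was not compared with the share among genes tested.

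Over all nuclei, 157 genes were higher and 255 lower after sevoflurane than with oxygen, of the 20777 tested (412 called, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 libraries per group). Among the risen genes, the guanine nucleotide exchange factor gene Arhgef33 (ENSMUSG00000054901, chromosome 17, 80307407 to 80400081) went from 7.76 ± 0.319 to 15.3 ± 2.21 CPM (SD, n = 3), a log2 fold change of 0.97 (SE 0.12). Klhl10 (ENSMUSG00000001558, chromosome 11, 100441917 to 100457022), which encodes an adaptor of a ubiquitin ligase, rose by 0.82 (SE 0.09) from 11.98 ± 0.946 to 21.1 ± 1.67 CPM. Sav1 (ENSMUSG00000021067, chromosome 12, 69965012 to 69987002), a scaffold of the growth-limiting Hippo pathway, fell by 1.16 (SE 0.15) from 33.3 ± 7.08 to 14.9 ± 1.02 CPM. Sytl5 (ENSMUSG00000054453, chromosome X, 9885622 to 9994543), an effector of vesicle-tethering Rab proteins, fell by 1.15 (SE 0.08), and the zinc finger gene Zbtb40 fell by 1.00 (SE 0.08). Their adjusted p-values were 0.0197 for Arhgef33 and Klhl10, 0.0219 for Sav1, 0.0103 for Sytl5 and 0.0124 for Zbtb40. The largest fall belonged to Ttr, the thyroid hormone carrier of the choroid plexus, at -6.86 (SE 0.95), and without the choroid plexus-like nuclei and clusters 16 and 40 it stood at -6.70 (adjusted p 0.0517). The remaining named rises, from Ano1 (1.41) and Cacng5 (1.05) to Hfm1 and Col26a1 (0.67 each), and the remaining named falls, from Gli3 (-1.09) and Rgs20 (-1.06) to Cobl and Mamdc2 (-0.91 each), had adjusted p-values of 0.0197 to 0.0498. The rises of Ano1, Ankfn1 (0.77) and Pld5 (0.70) depended on which nuclei were summed: without the choroid plexus-like nuclei and clusters 16 and 40, Ano1 stood at -0.01 and Pld5 at -0.04, and with equal class shares Ankfn1 stood at -0.11. Of 35 named calls over all nuclei, 26 stayed without those nuclei and 29 with equal class shares. Among the calls that ended were Col26a1 (0.44, adjusted p 0.142) and Mamdc2 (-0.64, adjusted p 0.071) without those nuclei. With equal class shares the calls of Mamdc2 (-0.47, adjusted p 0.068) and Rgs20 (-0.81, adjusted p 0.0693) ended. After the length correction, Ttr (-6.90), Gli3 (-0.93), Cobl (-0.76), Mamdc2 (-0.81), Hfm1 (0.72) and Col26a1 (0.78) had folds of similar size but adjusted p-values of 0.0502 to 0.0686, which ended their calls. With 1 library left out, 0 genes (without oxygen replicate 3) to 246 genes (without sevoflurane replicate 1) were called over all nuclei, and 1, 20, 30 and 141 without oxygen 1, oxygen 2, sevoflurane 2 and sevoflurane 3.

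**Figure D1:**
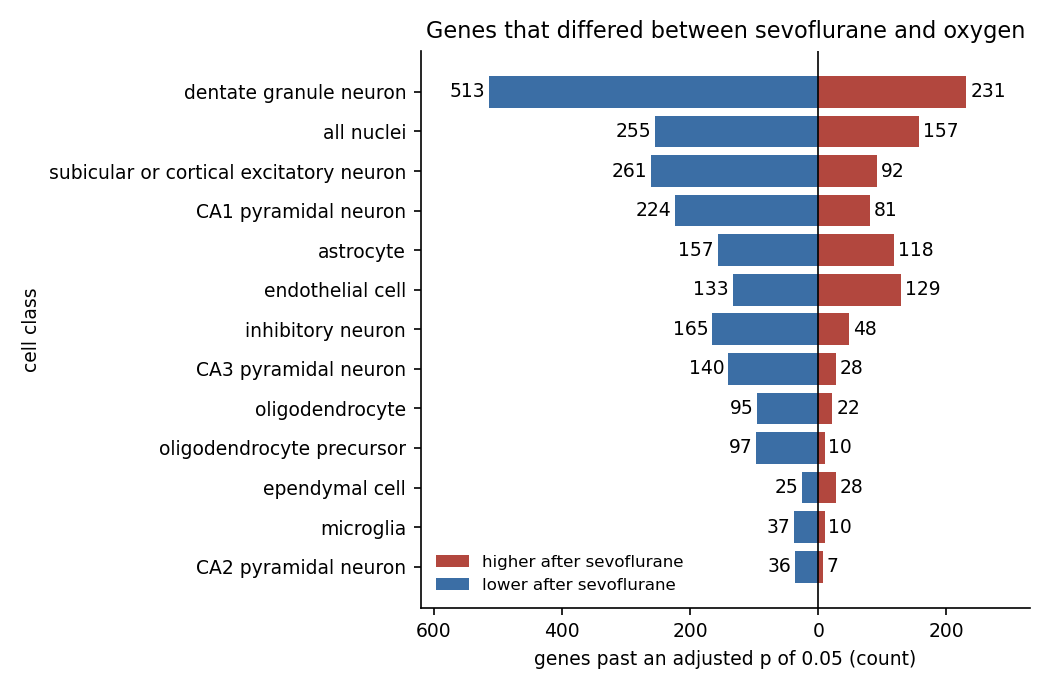
Bars give the number of genes past an adjusted p of 0.05 in each cell class and over all nuclei, higher after sevoflurane to the right and lower to the left. Dentate granule-like neurons had the most calls, 231 higher and 513 lower, and also the most summed UMIs of the classes.

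Dentate granule-like neurons, which relay cortical input into the hippocampus, gave the largest number of calls, 744 of 15988 genes tested, of which 231 rose and 513 fell, while with the length correction 53.6% of 470 calls were rises. This class also had the most summed UMIs, 10528400 to 15988500 per library, against 396844 to 669271 in microglia-like nuclei. The number of calls therefore does not rank the classes by the size of their response. Muc3a, a mucin gene, rose most among the named genes, by 1.74 (SE 0.21, adjusted p 0.00279) from 3.14 ± 0.418 to 10.6 ± 2.63 CPM (SD, n = 3). Arsg (ENSMUSG00000020604, chromosome 11, 109473374 to 109573330), a lysosomal sulfatase, rose by 1.33 (SE 0.15, adjusted p 0.00263), and Cacng5, a regulator of AMPA receptors, by 1.15 (SE 0.17, adjusted p 0.00541). The other named rises were Oacyl (1.32), Cstad (1.31), Arhgef33 (1.22), Cfap299 (1.00), Iqck (0.97), Catspere2 (0.91) and Pcolce2 (0.90). Sytl5 fell by 1.57 (SE 0.10, adjusted p 9.32e-05) from 45.1 ± 2.35 to 15.2 ± 1.44 CPM. Chst9 (ENSMUSG00000047161, chromosome 18, 15451924 to 15760157), a sulfotransferase for cell-surface sugars, fell by 1.26 (SE 0.10, adjusted p 0.000703) from 373 ± 14.7 to 156 ± 24.8 CPM. Trpc6, a calcium-permeable channel, fell by 1.04 (SE 0.14) from 419 ± 77.1 to 203 ± 26.2 CPM, and the neuronal adhesion gene Cntn6 fell by 1.55 (SE 0.23). The other named falls were Prr16 (-1.37), Vegfc (-1.33), Sav1 (-1.29), Cdh20 (-1.10), Atad2 (-1.10) and Atp6v1c2 (-1.08). Members of receptor and release lists fell by less: the GABA-A subunit gene Gabrb2 by 0.47 (SE 0.06), the glutamate receptor genes Grm5 by 0.46 (SE 0.06) and Grin2a by 0.35 (SE 0.05), and the calcium sensor of release Syt1 by 0.45 (SE 0.06). Predicted genes made up 76 of the 231 rises (32.9%) against 17.4% of the genes tested. With the length correction the calls of Prr16 (-1.18, adjusted p 0.0555) and Grin2a (-0.13, adjusted p 0.136) ended. Leaving out 1 library at a time, 218 (without oxygen 2) to 770 genes were called, with 269 without oxygen 3, 299 without oxygen 1 and 406 without sevoflurane 2.

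Falls also outnumbered rises in the other neuron classes, though with the length correction 55.4% of the calls in subicular or cortical excitatory-like and 45.9% in CA1-like neurons were rises. CA1 pyramidal-like neurons had 81 rises and 224 falls, subicular or cortical excitatory-like neurons 92 and 261, inhibitory-like neurons 48 and 165, CA3 pyramidal-like neurons 28 and 140, and CA2 pyramidal-like neurons 7 and 36. In CA1-like neurons the activity-induced receptor gene Nr4a2 rose by 1.14 (SE 0.18, adjusted p 0.0243) from 30.3 to 66.2 CPM and Fos by 1.54 (SE 0.30, adjusted p 0.0287), beside Muc3a (1.68), Fam107b (1.46) and Tiparp (1.21), while Sav1 (-1.21), Zbtb40 (-0.97), Tmod3 (-0.92) and Car4 (-0.89) fell. In CA3-like neurons the antiproliferative gene Btg2 rose by 1.43 (SE 0.29), with Nxpe2 (1.10), Slco5a1 (0.97) and Nr4a2 (0.96), and Sytl5 (-1.78), Sav1 (-1.30), Shisa9 (-1.27) and Zbtb40 (-1.12) fell. Inhibitory-like neurons gained Nrg4 (1.56), Pate2 (1.42), Arhgef33 (1.21) and Glis1 (1.09) and lost Gulp1 (-1.21), Sav1 (-1.21), Zbtb40 (-0.999) and Plxdc2 (-0.82). Subicular or cortical excitatory-like neurons gained the prostaglandin transporter gene Slco2a1 (1.59), Arhgef33 (1.39), Ccdc7b (1.34), Zbtb7c (1.23), Tiparp (1.11), Klhl10 (1.09), Spag6 (1.09), Ccdc13 (1.07), Acr (1.04) and Itga5 (1.04). They lost Sav1 (-1.36), Scpep1os (-1.18), Lhfp (-0.95), Ovol2 (-0.86), Chst9 (-0.82), Shc3 (-0.79), Wwc1 (-0.77), Cys1 (-0.77), Stard13 (-0.76) and Arhgef15 (-0.76). This class joins 7 clusters and held 920, 350 and 908 nuclei in the sevoflurane libraries and 724, 850 and 1005 in the oxygen libraries. The mix of clusters also differed: cluster 22 held 115, 19 and 95 nuclei in the sevoflurane libraries. CA2-like neurons gained Blnk (2.48), Fggy (2.32), Serinc2 (2.29) and Tll2 (1.56) and lost Rec114 (-1.33), Ntng1 (-1.24), Fgf1 (-1.02) and Nwd2 (-1.01). With the length correction the calls ended, at adjusted p-values of 0.0506 to 0.0779, of Btg2 in CA3-like (1.30), Serinc2 in CA2-like (2.25) and Tiparp (1.09), Ccdc13 (1.06), Acr (0.96), Ovol2 (-0.88), Stard13 (-0.59) and Arhgef15 (-0.80) in subicular or cortical excitatory-like neurons. With 1 library left out, the lowest counts were 39 in CA1-like, 68 in subicular or cortical, 101 in inhibitory-like and 33 in CA3-like neurons, each without oxygen 2, and 8 in CA2-like neurons without sevoflurane 3.

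Astrocyte-like nuclei raised their cholesterol synthesis genes after sevoflurane. The class had 118 rises and 157 falls, and 15 of the 21 members of the cholesterol synthesis list rose while 0 fell, with 19 risen when adjusted over the list alone. Cyp51 (ENSMUSG00000001467), a sterol demethylase, rose by 1.19 (SE 0.13, adjusted p 0.000176) from 50.8 ± 3.33 to 116 ± 3.66 CPM (SD, n = 3), and Fdft1 (ENSMUSG00000021273), which forms squalene, by 1.18 (SE 0.13, adjusted p 0.000176) from 68.9 ± 6.14 to 156 ± 13.05 CPM. The median member rose by 1.18 (camera FDR 9.98e-25), but with an estimated inter-gene correlation the list did not pass (p 0.0135, FDR 0.338). The 21 genes summed to 2023 CPM after sevoflurane and 963 CPM with oxygen. With 1 library left out, 13 to 17 members were called. In every other class 0 to 2 members rose and 0 fell.

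**Figure D2:**
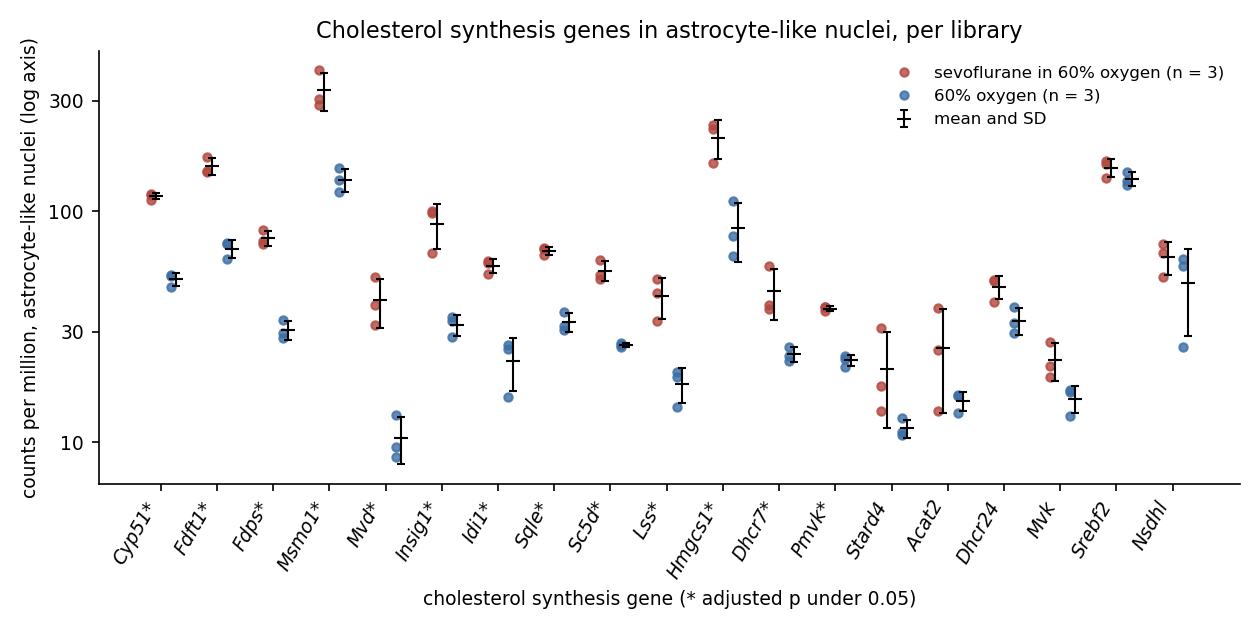
Points are the CPM of 19 cholesterol synthesis genes in astrocyte-like nuclei, per library on a log axis, with the mean and SD of 3 libraries beside them. The 3 sevoflurane libraries lie above the 3 oxygen libraries for each of the 13 called genes shown, marked with an asterisk.

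Other genes that rose in astrocyte-like nuclei included members of the glucocorticoid-responsive and p53 target lists. The kinase gene Sik1, induced by cAMP, rose by 2.65 (SE 0.34, adjusted p 0.000418) from 2.63 ± 0.658 to 16.4 ± 3.56 CPM, and Slc43a3 (2.38), Map3k6 (2.31) and Setdb2 (2.09) rose as well. Pdk4, which blocks the entry of pyruvate into mitochondrial oxidation, rose by 1.36 (SE 0.15, adjusted p 0.000176), together with the other glucocorticoid-responsive genes Arrdc2 (1.59) and Ddit4 (1.10), and the p53 targets Trp53inp1 (1.33) and Ccng1 (0.95) rose. The metabotropic glutamate receptor gene Grm3 fell by 1.71 (SE 0.23, adjusted p 0.0042) from 1070 ± 314 to 329 ± 89.6 CPM, and Zbtb40 (-1.60), Klf8 (-1.58) and Cdc42ep1 (-1.58) fell. The cystine transporter gene Slc7a11 fell by 0.89 (SE 0.19), a call that ended with the length correction (-0.72, adjusted p 0.135). After 1 library was left out, 75 (without oxygen 2) to 387 genes were called, with 138 without sevoflurane 2, 142 without oxygen 3 and 177 without oxygen 1.

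Endothelial-like nuclei, which line the vessels, had 129 rises and 133 falls among 8551 genes tested. The metalloprotease gene Adamts9 rose by 2.99 (SE 0.46, adjusted p 0.0143) from 30.3 ± 8.17 to 249 ± 144 CPM (SD, n = 3), Tnfrsf12a by 2.65 (SE 0.33, adjusted p 0.000389), the urokinase receptor gene Plaur by 2.63 (SE 0.37) and Maff by 2.39 (SE 0.34). The cell-cycle inhibitor gene Cdkn1a rose by 1.47 (SE 0.20, adjusted p 0.000246) from 145 ± 23.2 to 408 ± 93.5 CPM, with the metallothionein genes Mt2 (1.31) and Mt1 (1.05), Sgk1 (1.18), Nr4a1 (1.78) and Klf4 (1.51). The polyamine genes Odc1 and Sat1 rose by 1.73 (SE 0.36, adjusted p 0.00906) and 1.25 (SE 0.23, adjusted p 0.00424). The hypoxia gene Ankrd37 fell by 3.12 (SE 0.48, adjusted p 0.000716) from 37.3 ± 10.3 to 3.77 ± 1.97 CPM, Iigp1 by 2.60 (SE 0.46), St8sia4 by 2.23 (SE 0.23) and Ifit1 by 1.99 (SE 0.38). The clock output gene Dbp fell by 1.496 (SE 0.22), the drug efflux pump gene Abcg2 by 0.84 (SE 0.17), and the glucose transporter gene Slc2a1 rose by 0.64 (SE 0.17). Each library held 61 to 191 of these nuclei, and 99 (without oxygen 1) to 238 genes were called with 1 library left out, with 134 without oxygen 3. With the stricter nuclei filter only 4 genes were called. The median mitochondrial share of this cluster was 1.4%, above the 1% limit of that filter. Its 10 leading genes held 6 endothelial markers and also Rgs5, a marker of the pericyte list.

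Ependymal-like nuclei, which line the ventricles, had 28 rises and 25 falls. The nuclear receptor gene Nr4a3 rose by 3.54 (SE 0.37, adjusted p 9.86e-05) from 25.1 to 307 CPM, and Pros1 (2.32), Iffo2 (2.07) and Dusp10 (1.91) also rose. Egr1 rose by 1.66 (SE 0.31) and the amino acid transporter gene Slc7a5 by 1.88 (SE 0.46). Col8a1 (-3.14), Ahsa2 (-1.61), Rnf121 (-1.59) and Prrx1 (-1.59) fell. Col8a1 is also a leading gene of the choroid plexus-like cluster, which was absent from the sevoflurane libraries. After correction for length, Prrx1 (-1.59, adjusted p 0.0503) and Slc7a5 (1.83, adjusted p 0.0828) kept their folds and lost their calls. With 1 library left out, 23 (without oxygen 2) to 88 genes (without sevoflurane 1) were called, with 35 without oxygen 1, and the stricter nuclei filter left 10.

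Microglia-like nuclei lowered 37 genes and raised 10. The Schlafen genes Slfn9 and Slfn8, which are interferon-inducible, fell by 3.57 (SE 0.60, adjusted p 0.00211) and 2.50 (SE 0.27, adjusted p 0.000696), Slfn8 from 332 to 58.8 CPM, and Zbtb40 (-1.72) and Adamts16 (-1.69) fell. The carbohydrate kinase gene Fggy rose by 2.09 (SE 0.33), with Ddit4 (1.58), Cdkl3 (1.24) and Abhd15 (0.91). Oligodendrocyte-like nuclei had 22 rises and 95 falls: Adam11 fell by 1.99 (SE 0.16, adjusted p 8.48e-05) from 142 to 36.2 CPM, with Sav1 (-1.56), Tbc1d4 (-1.39) and Ninj2 (-1.27), and the antisense RNA St8sia3os rose by 2.21 (SE 0.34), with the mitochondrial folate enzyme gene Mthfd1l (1.23), Pnpla2 (1.21) and Snhg9 (1.01). Oligodendrocyte precursor-like nuclei had 10 rises and 97 falls, led by Gpatch4 (1.496), Mtfr1l (1.42), Nox1 (1.32) and Rcbtb2 (1.02) and by Dnah2 (-1.40), Sav1 (-1.25), Pacsin2 (-0.999) and Zfp934 (-0.95). With the length correction the calls of Ddit4 in microglia-like nuclei (1.39, adjusted p 0.134) and of Ninj2 (-1.18), Pnpla2 (1.12) and Snhg9 (0.75) in oligodendrocyte-like nuclei ended. All 8 genes named for oligodendrocyte precursor-like nuclei lost their calls too, with folds of similar size: Gpatch4 (1.40), Mtfr1l (1.30), Nox1 (1.41), Rcbtb2 (1.06), Dnah2 (-1.32), Sav1 (-1.31), Pacsin2 (-0.95) and Zfp934 (-0.89), at adjusted p-values of 0.056 to 0.152. With oxygen 2 left out, 10 genes were called in microglia-like, 8 in oligodendrocyte-like and 5 in oligodendrocyte precursor-like nuclei.

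Several gene sets moved the same way in many classes. Of 321 list tests, 78 passed camera at an FDR of 0.05, 52 up and 26 down, while with an estimated inter-gene correlation 0 passed at that FDR and 13 of the 78 had a p under 0.05. Immediate early genes passed upward in 9 of 13 sets of nuclei, with medians of 0.29 to 1.66 and the largest in ependymal-like nuclei (estimated-correlation p 0.00569). Glucocorticoid-responsive genes passed upward in 5 classes, with a median of 0.43 in astrocyte-like (estimated-correlation p 0.113) and 0.31 in endothelial-like nuclei (p 0.0386). Genes of the unfolded protein response, which relieves misfolding in the endoplasmic reticulum, passed downward in 6 sets of nuclei, with 4 called over all nuclei: Xbp1 (-0.56), Hsp90b1 (-0.47), Pdia4 (-0.67) and Pdia6 (-0.55). Cytosolic ribosomal proteins and complex I to V nuclear genes each passed upward in 12 sets of nuclei, with medians of 0.22 to 0.35 and 0.12 to 0.33, yet only 1 member, Rpl23 in oligodendrocyte precursor-like nuclei (0.75), was called, and this call ended with the length correction (0.56, adjusted p 0.110). Under the length correction, 11 of the 12 passes of the ribosomal list remained, 3 of the 12 of complex I to V, 8 of the 9 of immediate early genes, 2 of the 5 of glucocorticoid-responsive genes (astrocyte-like and endothelial-like) and all 6 of the unfolded protein response. Cholesterol synthesis passed upward in 7 sets, mitochondrially encoded genes in oligodendrocyte-like nuclei (median 0.26), apoptosis and p53 targets in astrocyte-like (0.30) and circadian clock genes in CA2-like nuclei (0.36); with the length correction the passes of the mitochondrial and p53 lists ended and the others remained. Interferon response genes passed downward in endothelial-like nuclei (median -0.57) and upward in astrocyte-like nuclei (0.38, 0 members called), and the pass in astrocyte-like nuclei ended with the length correction, while the difference between these classes was not tested.

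The list of ionotropic and metabotropic glutamate receptors passed downward in 10 sets of nuclei, namely all nuclei, 5 neuron classes and the astrocyte-like, oligodendrocyte-like, oligodendrocyte precursor-like and ependymal-like nuclei, and upward in endothelial-like nuclei (median 0.38), and GABA-A receptor subunits passed downward in 4 sets and upward in endothelial-like nuclei (0.32). With the length correction none of the downward passes of these 2 lists remained. Synaptic vesicle release passed downward in subicular or cortical excitatory-like (median -0.11) and upward in endothelial-like nuclei (0.21), two-pore potassium and HCN channels downward in subicular or cortical excitatory-like nuclei (-0.16), myelin genes downward in oligodendrocyte-like nuclei (-0.16), and blood-brain barrier genes downward over all nuclei (-0.22) and in endothelial-like nuclei (-0.34). Of these, the passes of synaptic vesicle release in subicular or cortical excitatory-like nuclei and of blood-brain barrier genes over all nuclei ended with the length correction. The lists of methionine salvage and polyamines, adenosine signalling and turnover, inflammatory cytokine and NF-kB genes, disease-associated microglia genes, reactive astrocyte genes, heat shock proteins, NRF2 antioxidant genes, hypoxia and glycolysis, and protein arginine methyltransferases and methylation passed camera in 0 sets of nuclei, with 8 of their 115 tests at an unadjusted p under 0.05 and a smallest FDR of 0.0503. Mtap, whose enzyme degrades S-methyl-5-thioadenosine, did not change detectably: over all nuclei it stood at 5.50 ± 0.401 CPM after sevoflurane and 5.28 ± 0.302 CPM with oxygen (log2 fold change 0.06, SE 0.11, adjusted p 0.808), and in the 8 classes where it was tested 0 passed, with 0 at an unadjusted p under 0.05.

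A small set of genes recurred across classes. Of 1764 genes called in at least 1 class, 233 were called in at least 3, and 30 rose in some classes and fell in others. Zbtb40 and Mllt3, a reader of histone acylation, fell in 8 classes each. Sav1, Stxbp4 and Lrfn5 fell in 7, and Shisa9, Ncam2, Setbp1, Igf1r and Arpp21 in 6. Klhl10 rose in 5 classes, Muc3a, Pate2, Arhgef33, Arsg and Ifrd1 in 4, and Nr4a3, Vmn2r56, Chil1 and Parpbp in 3. The length correction ended calls in 2 ways. Folds became smaller for Mllt3 (5 of 8 classes, in CA1-like neurons from -0.41 to -0.25), Ncam2 (5 of 6, in subicular or cortical excitatory-like neurons from -0.46 to -0.23), Igf1r (5 of 6, in dentate granule-like neurons from -0.38 to -0.19), Arpp21 (4 of 6, in CA1-like neurons from -0.36 to -0.24), Lrfn5 (3 of 7, in subicular or cortical excitatory-like neurons from -0.59 to -0.38), Stxbp4 (3 of 7, in dentate granule-like neurons from -0.50 to -0.36), Shisa9 (3 of 6, in inhibitory-like neurons from -0.39 to -0.23) and Setbp1 (2 of 6, in CA3-like neurons from -0.49 to -0.34). Folds stayed about as large, with adjusted p-values of 0.0543 to 0.0833, for Zbtb40 (2 of 8, in oligodendrocyte-like nuclei from -0.90 to -0.86), Sav1 (1 of 7, in oligodendrocyte precursor-like nuclei from -1.25 to -1.31), Klhl10 (2 of 5, in CA3-like neurons from 0.71 to 0.67), Ifrd1 (1 of 4, in subicular or cortical excitatory-like neurons 0.49 in both fits), Nr4a3 (2 of 3, in CA3-like neurons 0.44 in both fits), Chil1 (2 of 3, in CA1-like neurons from 1.85 to 1.77), Vmn2r56 (1 of 3, in subicular or cortical excitatory-like neurons 1.66 in both fits) and Parpbp (1 of 3, in inhibitory-like neurons from 1.56 to 1.57).

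Genes that fell were long. In dentate granule-like neurons the genes called lower had a median span of 195 kb, those called higher 37.6 kb and all genes tested 24.2 kb. Among genes with a mean log2 CPM above 3, 152 of the 500 over 300 kb were called lower (30.4%), against 12 of 1698 under 10 kb (0.707%). Across genes, which are not independent replicates, the log2 fold change fell with span in dentate granule-like neurons (Spearman -0.40) and over all nuclei (-0.42) and hardly in endothelial-like nuclei (-0.02). Each library's slope on span was taken on the deviation of its log2 CPM from the gene's mean over the 6 libraries. The mean slopes of the groups therefore mirror each other, and only differences between libraries can be read. In dentate granule-like neurons the slopes were -0.121, -0.117 and 0.0219 after sevoflurane and 0.0755, 0.103 and 0.0376 with oxygen. They lay apart between the groups (exact permutation test, two-sided, p 0.10, the smallest possible). The slopes overlapped between the groups in oligodendrocyte-like, astrocyte-like, inhibitory-like and CA3-like nuclei (same test, p 0.2 each) and in endothelial-like nuclei. With the length correction, 470 genes were called in dentate granule-like neurons and 53.6% of them rose, against 231 of 744 without it, and over all nuclei 218 were called and 57.8% rose, against 38.1%. In the other classes the share of rises went from 42.9 to 49.3% in astrocyte-like, 49.2 to 50.7% in endothelial-like, 9.3 to 12.5% in oligodendrocyte precursor-like, 18.8 to 29.0% in oligodendrocyte-like, 26.6 to 45.9% in CA1-like, 26.1 to 55.4% in subicular or cortical, 22.5 to 41.8% in inhibitory-like, 16.7 to 32.2% in CA3-like, 21.3 to 31.7% in microglia-like, 52.8 to 75.6% in ependymal-like and 16.3 to 27.3% in CA2-like nuclei.

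**Figure D3:**
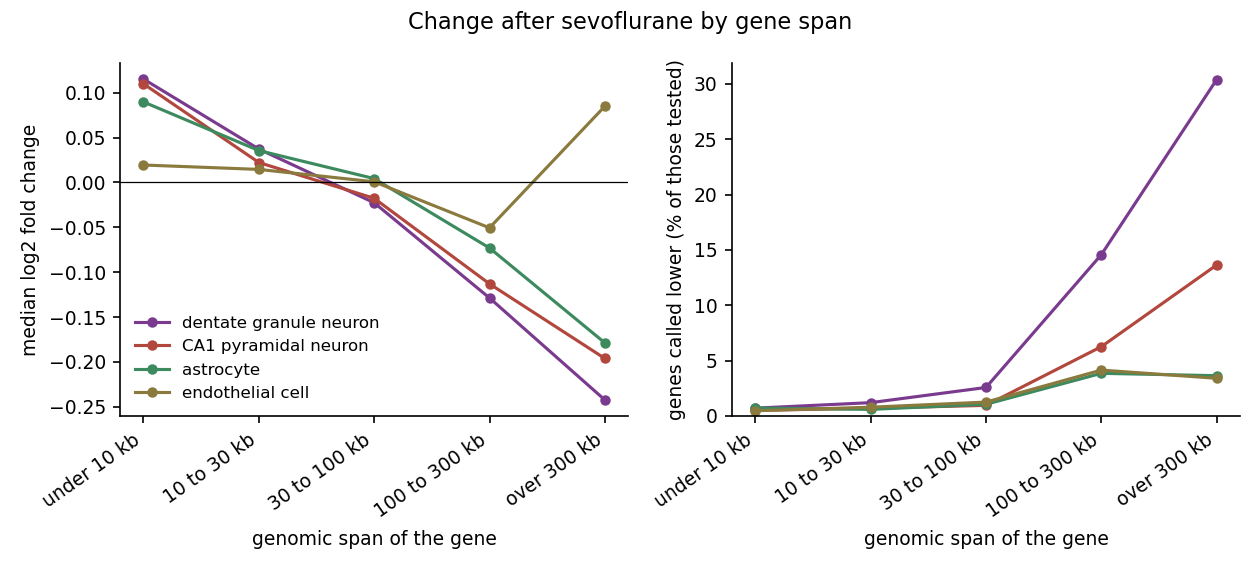
Lines give, for bins of genomic span, the median log2 fold change (left) and the percentage of genes called lower (right) in 4 classes. Only tested genes with a mean log2 CPM above 3 are included. In dentate granule-like neurons the percentage goes from 0.707% under 10 kb to 30.4% over 300 kb.

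The response differed between dentate granule-like and oligodendrocyte-like nuclei in 51 of 12335 genes (limma, adjusted p under 0.05), 26 with a higher and 25 with a lower change in granule-like neurons. Adam11, which fell in oligodendrocyte-like nuclei, had a difference of 1.97 (SE 0.17, adjusted p 0.000825). Arsg, which rose in granule-like neurons, had a difference of 1.44 (SE 0.20, adjusted p 0.0103), and St8sia3os one of -1.69 (SE 0.31, adjusted p 0.0360). Leaving 1 library out, 4 (without oxygen 2) to 81 genes (without sevoflurane 1) were called, with 12 without oxygen 3, 17 without sevoflurane 2 and 24 without sevoflurane 3.

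Choroid plexus-like nuclei, which make cerebrospinal fluid, were seen in the oxygen libraries only. They numbered 59 of 7783 (0.758%, 95% Wilson interval 0.588 to 0.977%), 16 of 8813 (0.182%, 0.112 to 0.295%) and 99 of 7734 (1.28%, 1.05 to 1.56%) in the oxygen libraries and 0 in each sevoflurane library, which allows a share of up to 0.0308, 0.0336 and 0.0336%. Cluster 16, whose leading genes include Ano1, Ankfn1 and Pld5 and which expressed the inhibitory markers Gad1 and Gad2, made up 2.35 ± 0.150% of nuclei after sevoflurane and 0.321 ± 0.096% with oxygen (SD, n = 3). Cluster 40, with Ebf2 and Ebf3 among its leading genes, made up 0.523 ± 0.157% and 0.019 ± 0.023%. For these 3, the groups did not overlap and the exact permutation test gave its smallest p, 0.10. Of all 34 named classes and unnamed clusters, 6 (17.6%) did not overlap, where chance gives 10%. Astrocyte-like nuclei made up 7.16 ± 2.36% after sevoflurane and 8.93 ± 0.191% with oxygen (exact permutation p 0.10), a lower mean that rests on sevoflurane replicate 1 (4.44%). The shares of the other named classes overlapped between the groups, among them dentate granule-like neurons with 20.3 ± 1.86% and 17.5 ± 4.39%. On class counts edgeR called 0 of the 16 named classes, with 1 at an unadjusted p under 0.05, and the smallest adjusted p was 0.059, for choroid plexus-like nuclei (unadjusted p 0.00369).

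**Figure D4:**
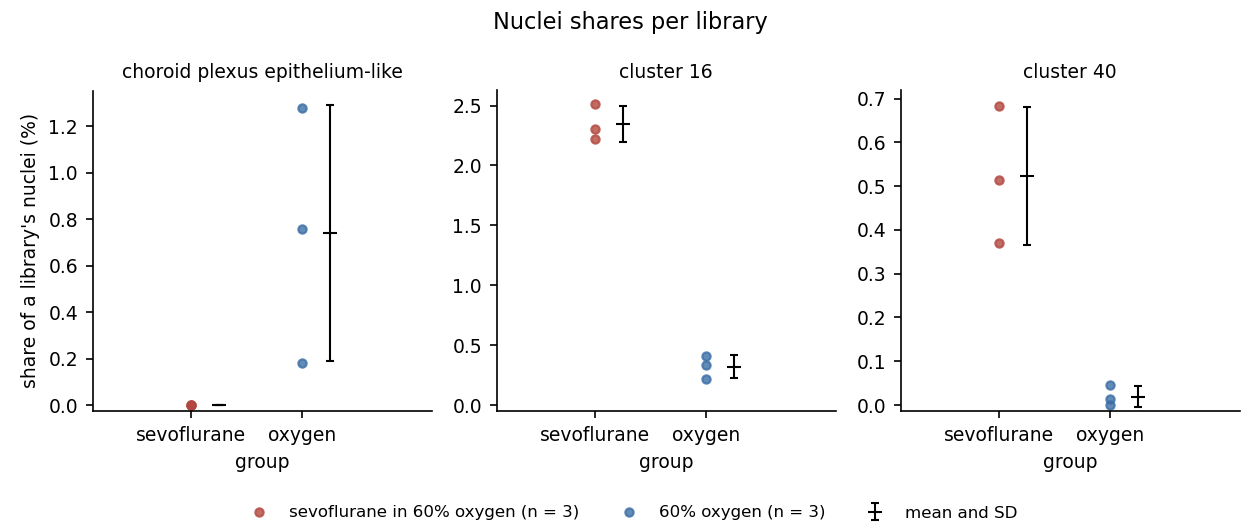
Points are the share of each library's nuclei, in percent, that fell in the choroid plexus-like class, cluster 16 and cluster 40, with the mean and SD of 3 libraries. Choroid plexus-like nuclei were 0 in the sevoflurane libraries, and clusters 16 and 40 averaged 2.35 and 0.523% there.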

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

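Among the tests of this part, the astrocyte difference, the Ttr test, the mitochondrial share and the count of falls that stay after the length correction were chosen only after the results had been seen. The coarser clustering and the thinning were settings fixed beforehand, but their use as tests of an explanation was chosen afterwards.

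The response of 51 genes differed between dentate granule-like and oligodendrocyte-like nuclei, tested as a difference within each library. In the added comparison, 211 genes responded differently in astrocyte-like and dentate granule-like nuclei, 129 with a higher and 82 with a lower change in astrocyte-like nuclei. Of the 21 cholesterol synthesis genes, 14 had a different response in these 2 classes. Cluster 16 made up 2.35% and cluster 40 0.523% of the nuclei in the sevoflurane libraries, and these nuclei received no name and were not tested for genes as a class of their own.

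Choroid plexus-like nuclei were seen only with oxygen, and clusters 16 and 40 almost only with sevoflurane. For the choroid plexus-like nuclei a dependence on the clustering is argued against, since the coarser resolution also placed 0 choroid plexus-like nuclei in the 3 sevoflurane libraries, while clusters 16 and 40 were not followed there. Ttr in oligodendrocyte-like nuclei was 601 ± 536 CPM with oxygen and 6.83 ± 0.164 CPM after sevoflurane, 87.9 times higher, so the free RNA went with the nuclei, as either neighbouring tissue taken along in different amounts or a loss of choroid plexus under treatment would have it. In clusters 16 and 40, 4 of 7 septal markers (Zic1, Zic2, Zic4 and Zic5), all of the same gene family, were at least 2 times higher than in all other nuclei. Only Zic1 and Zic4 also reached 10 CPM in both, and Zic2 and Zic5 rest on 6 and 4 UMIs in cluster 40. Crhr2 and Drd3 were that much higher in cluster 16 only (9.7 and 4.84 CPM). In cluster 40 they stood at 1.09 and 0 CPM, against 1.95 and 0.083 CPM in all other nuclei. Trhr was not in either cluster (9.33 and 6.53 against 7.04 CPM). A septal source of cluster 40 therefore rests on Zic genes alone. Different amounts of neighbouring tissue may explain both findings. An effect of sevoflurane on these cells stays open, since the labels give no record of the dissections.

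Long genes fell in dentate granule-like neurons. A smooth length trend of the libraries is argued against as the whole cause for 202 of the 513 falls, which passed with the trend removed, while the other 311 lost their call and cannot be told apart from such a trend, because its slopes themselves separate the groups (their median of -0.18 with the trend removed is set in part by that choice of genes). Of the 513 falls, 89.1% passed after thinning to the smallest library. Thinning of summed counts leaves the expected CPM of each gene unchanged and can end calls only through lower counts. This result therefore does not decide whether unequal summed totals played a part. Thinning also cannot test a difference in depth per nucleus. The median granule-like nucleus held 6291.5, 6464 and 7904.5 UMIs in the sevoflurane libraries and 7881.5, 7593 and 6902.5 in the oxygen libraries. Sevoflurane replicates 1 and 2, with the lowest medians, also had the only negative slopes on span. Sevoflurane replicate 3, with the highest median, still had a slope below those of all oxygen libraries. A difference in depth per nucleus therefore stays open. More RNA from outside the nucleus in the sevoflurane libraries stays open: the mitochondrial share was 0.0693 percentage points higher there (0.288 ± 0.0428% against 0.218 ± 0.101%, exact permutation p 0.4, n = 3). An effect of sevoflurane on the transcription of long genes was not tested separately and is among the open explanations, as a hypothesis.

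Cholesterol synthesis genes rose in astrocyte-like nuclei. A length trend is argued against, since 15 members passed with the trend removed. Free RNA shared by all classes is argued against, since the median member rose by 1.09 more in astrocyte-like than in dentate granule-like nuclei. The median log2 fold change was 1.18 in astrocyte-like nuclei and -0.22 to 0.40 in the other tested classes. Nuclei of another kind inside the astrocyte-like cluster stay open, since a comparison between classes does not look inside the cluster. A single library is argued against, since at least 13 members passed with any 1 library left out, and 17 without sevoflurane replicate 1, the library with the female pattern. A response of astrocytes to sevoflurane may underlie the rise, a hypothesis found and tested on the same data.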

How the results depend on the processing

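The length correction and the settings without choroid plexus-like nuclei and clusters 16 and 40 or without cluster 2 were chosen only after the results had been seen. Where a value below differs from the reported one, the cause was not tested, unless fewer nuclei, genes or libraries explain it by construction.

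DESeq2 size factors kept each count of genes within 1.5 times, and of 364 called named results 363 stayed past the threshold. No named called result turned its direction except those of 3 genes over all nuclei: without the choroid plexus-like nuclei and clusters 16 and 40, Ano1 stood at -0.0107 and Pld5 at -0.0444, and with equal class shares Ankfn1 stood at -0.11, while the list of glutamate receptors turned upward in oligodendrocyte-like nuclei with the length correction (FDR 0.88). Equal class shares gave 909 genes over all nuclei.

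With no filter on low counts, 404 genes were called in oligodendrocyte-like, 756 in CA1-like, 1010 in subicular or cortical excitatory-like, 589 in astrocyte-like, 695 in inhibitory-like, 552 in CA3-like, 92 in microglia-like, 437 in endothelial-like, 133 in ependymal-like and 136 in CA2-like nuclei. The DESeq2 test called 1413 over all nuclei, 537 in CA1-like, 359 in inhibitory-like, 269 in CA3-like, 168 in endothelial-like and 35 in ependymal-like nuclei. In simulated data over all nuclei, 24.8% of its calls were false, against 11.7% for edgeR. Labelled sex as a term gave 248 over all nuclei, 490 in dentate granule-like, 177 in CA1-like, 202 in subicular or cortical excitatory-like, 89 in CA3-like, 71 in oligodendrocyte precursor-like and 28 in CA2-like nuclei, and those labels did not match expression in 3 libraries. An exchange among these 6 libraries alone cannot account for all of this mismatch, since 2 libraries are labelled female and 1 had the female pattern. A wrong sex label, or an exchange that explains part of the mismatch, was not tested. An exchange that crossed the groups would change what every comparison means. The given division called 412 genes over all nuclei and every other division at most 1. A crossing of single libraries would not predict this if treatment drove the calls.

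The replicate number was also used as a block, although the numbers showed no pairing over all nuclei. With this block 65 genes were called over all nuclei, 237 in dentate granule-like, 103 in CA1-like, 56 in inhibitory-like, 94 in CA3-like and 50 in oligodendrocyte precursor-like nuclei. The same block in edgeR on class counts called 1 class, choroid plexus-like nuclei (adjusted p 0.0316).

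The length correction gave 218 over all nuclei, 470 in dentate granule-like, 62 in oligodendrocyte-like, 135 in CA1-like, 130 in subicular or cortical excitatory-like, 122 in inhibitory-like, 87 in CA3-like, 16 in oligodendrocyte precursor-like and 22 in CA2-like nuclei, and 50 passing list tests. It kept 228 of the 364 named calls. Thinning gave 215 in subicular or cortical excitatory-like, 25 in microglia-like, 170 in endothelial-like and 23 in CA2-like nuclei. The stricter nuclei filter gave 4 in endothelial-like and 10 in ependymal-like nuclei, where fewer nuclei remained. Their median mitochondrial shares, 1.4 and 1.42%, lay above the 1% limit of that filter. Whether the lost calls came from fewer nuclei alone or from which nuclei were removed was not tested. At Leiden resolution 0.5, 0 genes were called in CA2-like nuclei. A mean of at least 20 CPM left 33 genes for the difference between granule-like and oligodendrocyte-like nuclei. With an estimated inter-gene correlation 0 list tests passed. With fry 7 passed, 6 of them among the 78 that passed camera.

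With 1 library left out, the counts ranged from 0 to 246 over all nuclei, 218 to 770 in dentate granule-like, 8 to 170 in oligodendrocyte-like, 39 to 430 in CA1-like, 68 to 259 in subicular or cortical excitatory-like, 75 to 387 in astrocyte-like, 101 to 199 in inhibitory-like, 33 to 138 in CA3-like, 10 to 58 in microglia-like, 5 to 157 in oligodendrocyte precursor-like, 99 to 238 in endothelial-like, 23 to 88 in ependymal-like and 8 to 37 in CA2-like nuclei. The difference between classes ranged from 4 to 81 genes, the passing list tests from 54 to 101, and the called classes stayed at 0. Over these fits 1278 of 2184 named calls stayed past the threshold and 0 turned. In simulated endothelial-like nuclei, the only small class simulated, 51.5% of changes of 1 and 10.1% of changes of 0.5 were recovered.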

Other observations

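The tests of this part on the splits of the libraries were chosen only after the results had been seen, and the genes and clusters singled out here were chosen after their values were seen. Within dentate granule-like neurons, a small cluster of 95 nuclei had Fosb, Arc, Inhba and Atf3 among its leading genes, which mark recent or strong activity. It held 37, 21 and 13 nuclei in the sevoflurane libraries and 2, 11 and 11 in the oxygen libraries. The larger cluster held 98.7% of the granule-like nuclei after sevoflurane and 99.4% with oxygen. As a share of the granule-like nuclei the small cluster made up 1.75, 1.13 and 0.80% after sevoflurane and 0.193, 0.566 and 0.830% with oxygen, so the groups overlap, and no test was made of it.

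Polyamine synthesis releases S-methyl-5-thioadenosine, the metabolite of the study's title, while polyamine breakdown does not. In endothelial-like nuclei a gene of each arm rose: Odc1, which opens synthesis, from 13.6 ± 4.56 to 47.5 ± 14.5 CPM (SD, n = 3) and Sat1, which marks polyamines for breakdown or export, from 70.7 ± 4.49 to 177 ± 63.8 CPM. The list of methionine salvage and polyamines as a whole did not pass in these nuclei (camera FDR 0.204). In dentate granule-like neurons 1 gene of the list was called, Ahcyl2, which fell by 0.29 (SE 0.07, edgeR adjusted p 0.0436), and this call ended with the length correction (adjusted p 0.285) and with the replicate block (0.110).

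Predicted genes made up 32.9% of the rises in dentate granule-like neurons and 17.4% of the genes tested, a difference that was not tested. The share among the rises was also above that among the genes tested over all nuclei (43.3 against 24.6%) and in 8 other classes, about equal in astrocyte-like nuclei (9.32 against 9.46%) and below it in endothelial-like (1.55 against 3.40%) and CA2-like nuclei (0 of 7 rises). A hypothesis was that transcription read on past the end of an upstream gene into them, which would place the risen ones close downstream of a protein-coding gene. Of 76 risen predicted genes, 21 (27.6%) lay within 50 kb downstream of one on the same strand, against 931 of 2689 others (34.6%). The ratio of 0.798 (95% interval 0.553 to 1.15, Fisher's exact test, two-sided, p 0.223) was lower and not higher, so the values argue against this explanation.

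Markers of other cell types inside a class differed without overlap between the groups in 60 of 264 pairs of list and class (22.7%, where chance gives 10%, and 13.7 to 24.8% of all genes in these classes did not overlap either), and were higher after sevoflurane in 18 of them. The pairs were spread over all 12 classes, with 8 of 22 in dentate granule-like, 7 each in CA1-like and CA3-like, 6 each in subicular or cortical excitatory-like, astrocyte-like and ependymal-like and 5 in endothelial-like nuclei.

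The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05, and for each count only 1 division, the real one, gave as many genes. The real count and the highest of the other divisions were 412 and 1 over all nuclei, 744 and 3 in dentate granule-like, 117 and 4 in oligodendrocyte-like, 305 and 1 in CA1-like, 353 and 1 in subicular or cortical excitatory-like, 275 and 1 in astrocyte-like, 213 and 1 in inhibitory-like, 168 and 2 in CA3-like, 47 and 2 in microglia-like, 107 and 3 in oligodendrocyte precursor-like, 262 and 1 in endothelial-like, 53 and 1 in ependymal-like and 43 and 8 in CA2-like nuclei, and 51 and 3 for the difference between granule-like and oligodendrocyte-like nuclei.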
